A study of Homo sapiens with 24 samples.

How the data were processed

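Total RNA and RNA from polysomal fractions were sequenced from 2 human lung cancer cell lines, A549 and H460. Each line received a control siRNA (siNT) or an siRNA against RICTOR (siRIC), which gave 8 groups of 3 libraries. Cells were grown in RPMI with 10% FBS and RNA was isolated with TriPure, per the labels' protocols. The labels name polyA RNA as the molecule, while their protocol names a stranded total RNA kit with ribosomal RNA depletion, so which RNA entered the libraries was not settled here. The submitters' processing notes name bcl2fastq 2.20 and the genome build GRCh38. The aligner settings, the annotation, the version of the quantification tool and any filters were not given in the sources used here.

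The authors deposited a single table of estimated counts per gene, named as merged salmon counts, with 1 column per library and no normalization. The table held 60666 genes, of which 60437 IDs matched a gene name, and no column belonged to another sample. Of the values, 9.40% were not whole and 95.3% lay within 0.002 of a whole number. Library totals ranged from 19087204 to 26550160 estimated counts. Replicate libraries of every group differed by more than sampling noise, with chi-square values per degree of freedom from 9.42 to 200, so none was treated as a library deposited more than once. This does not show that they came from separate cultures. How estimated counts were divided between near-identical genes was not given, so levels of close paralogs such as AKR1C1, AKR1C2 and AKR1C3 and of ribosomal protein genes with many pseudogenes are uncertain. Gene positions were taken from a RefSeq annotation of the same genome build.

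Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and differences were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. The 12 libraries of a line were fitted together, and all 24 libraries were fitted together for the mean of both lines and for the difference between lines. These fits had 8 and 16 residual degrees of freedom. Log2 fold changes are given with a standard error (SE), taken as the absolute change divided by the square root of its F statistic. This SE rests on the spread over all libraries of a fit, with information shared between genes. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The change in the polysomal-to-total ratio was tested as an interaction in the same model. There were 14 comparisons. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

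The groups, tests, alternatives, 34 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the 33 lists with 5 or more measured members in each comparison, which left out S1P receptors. Camera with an estimated correlation and fry were run beside it. Of the 462 list tests over all comparisons, 108 passed with the preset correlation and 10 of those with the estimated correlation. Named genes were RICTOR, ARNT and HIF1A in each siRIC comparison, then the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM, a standard symbol and the same sign in all 3 pairs of equal number, and 2 to 4 members with the smallest p of each list described. For polysomal against total RNA only list members were named, and for the difference between lines the 4 largest differences in each direction. Some genes that this rule takes are not reported here.

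Replicate numbers pair the samples of a line because the labels give each replicate as a batch, and "number" means this replicate number throughout. Deviations from the group means correlated between libraries of the same number with r from 0.0278 to 0.280 in A549 and from 0.0675 to 0.748 in H460, while libraries of different numbers correlated with at most 0.166. Between H460 siNT and siRIC libraries of the same number, r was 0.472 to 0.748 in polysomal RNA and 0.0675 to 0.242 in total RNA. Deviations within a group offset each other, so r of equal and of different numbers are not independent. The library names carry other numbers, 3, 4 and 6 in A549 and 4, 6 and 7 in H460, and what these mark is not given in the sources used here. Numbers 4 and 6 occur in both lines, as replicates 2 and 3 of A549 and 1 and 2 of H460, and no fit had a block across lines. In a check added after seeing the data, the 8 pairs of A549 and H460 libraries sharing such a name number had r from −0.0408 to 0.153, and the 28 other pairs of the same treatment and fraction −0.357 to 0.388. The reported fits had no block and so ignored this pairing. Their errors and p-values therefore include any spread shared between libraries of the same number. A fit with the number as a block was fixed as an alternative, with 6 residual degrees of freedom per line. Other alternatives were DESeq2 1.42.0, DESeq2 size factors, no filter on low counts, removal of mitochondrial and structural RNAs, fits of only the groups compared, a block within cultures for the ratio, all 24 libraries in the fit of the ratio, and leaving out each library. After seeing the data, 4 alternatives were added: the block with only the groups compared, the fit without the 2 H460 polysomal libraries of number 3, both the block and their removal, and list tests without the A549 siRIC polysomal library of number 1. The block with only the groups compared left 2 residual degrees of freedom in a single line and 4 in total RNA of both lines. A total and a polysomal library of the same line, siRNA and number are called a culture, although the labels do not say that both came from 1 culture.

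The tests were checked on simulated counts with 200 changed genes, each with a mean of at least 5 CPM. Counts were drawn from the means of the real libraries, taken per line over both fractions. Libraries were drawn independently with the spread of the fits without a block. Spread shared between libraries of the same number was therefore not simulated, and recovery in the real data may differ. Of 67 genes changed 2-fold, 86.6% were recovered in A549 total RNA, 94.0% in A549 polysomal RNA and 47.8% for the A549 ratio. In H460 the corresponding values were 23.9%, 35.8% and 5.97%, and for the mean of both lines they were 95.5%, 94.0% and 58.2%. For polysomal against total RNA they were 89.6% in A549 and 20.9% in H460, and for the difference between lines 22.4% in total, 26.9% in polysomal RNA and 1.49% for the ratio.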

Results

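Total RNA and polysomal RNA were sequenced from A549 cells, a human lung adenocarcinoma line, and H460 cells, a human large cell lung carcinoma line, after transfection with a control siRNA (siNT) or an siRNA against RICTOR (siRIC). RICTOR is the defining subunit of mTORC2, the mTOR complex that phosphorylates AKT. The design asked how depletion of RICTOR altered mRNA levels and the mRNAs bound to several ribosomes, with particular interest in ARNT and in sphingolipid genes. Each of the 8 groups held 3 libraries. Numbers given for libraries are their replicate numbers, 1 to 3, which the labels give as batches and which were paired within a line. Library totals ranged from 19087204 to 26550160 estimated counts. Mitochondrially encoded genes took 16.8% ± 1.49 (SD, n = 3) of the counts in A549 siNT total RNA and 3.28% ± 0.823 in A549 siNT polysomal RNA, and 15.6% ± 1.88 and 3.21% ± 0.935 in the corresponding H460 groups. Errors of log2 fold changes are SEs derived from the F statistics of the fits, with n = 3 libraries per group throughout.

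RICTOR (ENSG00000164327, GRCh38 chromosome 5, 38937920 to 39074399) was lower in each siRIC library than in each siNT library of the same line and fraction, which checks the labels. In A549 total RNA its level was 31.5, 26.1 and 33.8 CPM with siNT and 12.4, 9.97 and 12.6 CPM with siRIC, in the order of the replicate numbers. In A549 polysomal RNA it was 25.4, 19.97 and 27.3 CPM against 12.03, 4.96 and 8.71 CPM. The corresponding values in H460 were 18.7, 18.97 and 17.9 against 5.66, 7.23 and 6.38 CPM in total RNA, and 12.2, 10.5 and 24.2 against 3.38, 3.70 and 5.48 CPM in polysomal RNA. ARNT (ENSG00000143437, chromosome 1, 150809713 to 150876599), the dimerization partner of HIF1A and AHR, was likewise lower in each siRIC library. Its levels in A549 were 29.4, 27.9 and 30.1 against 18.5, 14.3 and 20.1 CPM in total RNA and 26.6, 30.2 and 23.3 against 11.1, 13.4 and 16.3 CPM in polysomal RNA. In H460 they were 28.1, 24.6 and 25.3 against 18.4, 17.7 and 17.9 CPM in total RNA and 19.95, 19.2 and 26.0 against 11.8, 14.3 and 14.9 CPM in polysomal RNA.

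**Figure D1:**
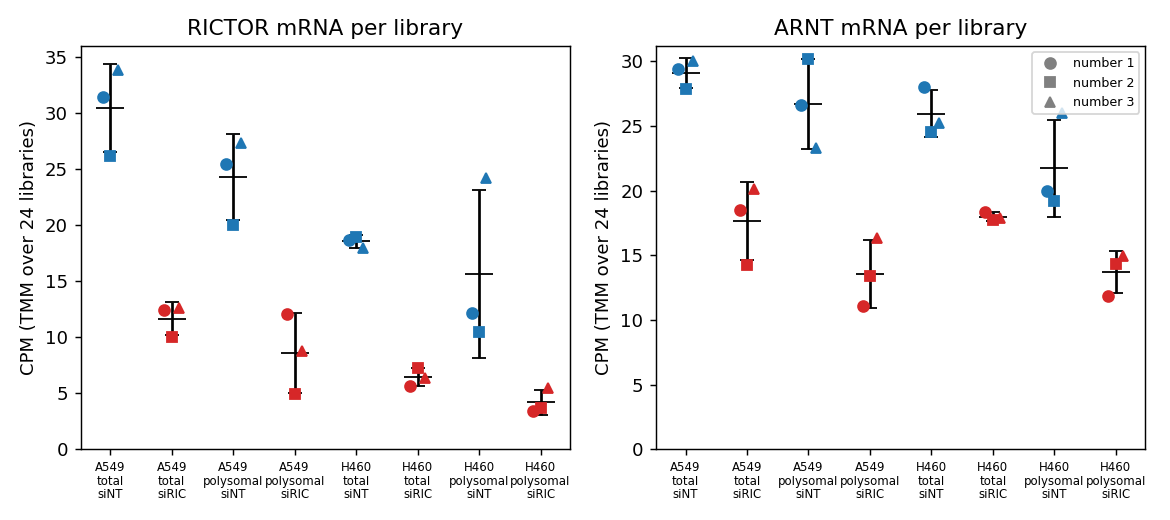
RICTOR and ARNT in CPM (vertical axis from 0) in each of the 24 libraries by line, fraction and siRNA (horizontal axis), with blue for siNT, red for siRIC, a symbol for each replicate number, and bars for the mean ± SD (n = 3). RICTOR in A549 total RNA lay between 26.1 and 33.8 CPM with siNT and between 9.97 and 12.6 CPM with siRIC.

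Polysomal RNA of A549 siNT cells was compared with total RNA to describe what the polysomal fraction held. All 13 mitochondrially encoded mRNAs, which are translated inside the organelle, were lower in polysomal RNA, among them MT-ND4L at −5.27 ± 0.26 (adjusted p = 3.37e-09) and MT-ND6 at −3.68 ± 0.17 (adjusted p = 1.94e-09). Nuclear noncoding RNAs were also lower, with 11 of 13 called over all genes and 12 adjusted over the list alone, including MALAT1 at −2.75 ± 0.26 and NEAT1 at −2.13 ± 0.23. Of the snoRNA host transcripts, 11 were called lower, including SNHG14 at −1.67 ± 0.15, and 12 were lower adjusted over the list alone. In contrast, 49 nuclear genes of oxidative phosphorylation were called higher, 57 adjusted over the list alone with 1 lower, led by UQCRC1 at 1.59 ± 0.13. Mitochondrial ribosomal protein genes behaved alike, with 44 called higher, 46 adjusted over the list alone with 1 lower, and MRPL28 at 1.63 ± 0.15. Glycolytic genes had 13 higher, 14 adjusted over the list alone, including PFKL at 1.33 ± 0.15 and ALDOA at 1.23 ± 0.17.

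In all, 2824 genes were higher and 2890 lower in A549 polysomal RNA, and 16 gene lists passed camera, of which 4 passed with an estimated correlation. Adjusted p was 6.72e-16 for the mitochondrially encoded genes, 7.41e-07 for nuclear noncoding RNAs, 1.21e-05 for snoRNA hosts, 6.72e-16 for oxidative phosphorylation, 2.63e-14 for mitochondrial ribosomal proteins and 4.14e-06 for glycolysis. With an estimated correlation these were adjusted p = 0.157, 0.0486, 0.263, 0.263, 0.304 and 0.263, respectively. Cholesterol synthesis (median 0.66), NRF2 targets (0.63) and lysosomal genes (0.40) also passed, with adjusted p = 0.0323, 0.0323 and 0.0486 with an estimated correlation. Cytosolic ribosomal protein genes had a median of 0.10 (adjusted p = 0.220), with 10 members called higher and 3 lower.

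In H460 siNT cells, polysomal RNA differed from total RNA in 1816 higher and 1531 lower genes. All 13 mitochondrially encoded mRNAs were lower, including MT-ND4 at −3.22 ± 0.33 and MT-ND2 at −2.81 ± 0.20, and so were 6 of 12 nuclear noncoding RNAs (8 adjusted over the list alone), with NEAT1 at −1.60 ± 0.33. Of 72 nuclear genes of oxidative phosphorylation, 62 were higher (66 adjusted over the list alone), with NDUFA9 at 1.51 ± 0.16, and 44 mitochondrial ribosomal protein genes were higher (47 adjusted over the list alone), with MRPL13 at 1.52 ± 0.15. Cytosolic ribosomal protein genes had a median of 0.58, and 38 of 79 were called higher (45 adjusted over the list alone), including FAU at 1.45 ± 0.24 and RPL24 at 1.00 ± 0.15. Glycolytic genes had 10 called higher, and 11 higher and 1 lower adjusted over the list alone. Camera gave adjusted p = 6.75e-16, 0.00154, 2.50e-29, 6.27e-23, 4.90e-13 and 4.00e-05 for these lists in that order. None passed with the correlation estimated from the data, with adjusted p = 0.160, 0.389, 0.160, 0.160, 0.428 and 0.381 with an estimated correlation.

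The H460 polysomal libraries of number 3 stood apart from the others of that line. The profile of polysomal-to-total ratios of these cultures correlated across genes, which are not independent replicates, with the other H460 cultures at a mean r of 0.449 (siNT) and 0.498 (siRIC), while the remaining H460 cultures had 0.559 to 0.575. The median log2 ratio of glycolytic genes was 0.270 and 0.441 in the number-3 H460 cultures and 0.777 to 1.08 in the other H460 cultures, and the H460 siNT polysomal library of number 3 had the highest RICTOR level of its group, 24.2 CPM. Without both libraries, 3647 genes were higher and 3384 lower in H460 polysomal RNA, 7031 in all against 3347 with them. With number as a replicate block the count was 5187. Leaving out the H460 siNT total library of number 1, 2 or 3 gave 1931, 1941 and 1832 genes.

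**Figure D2:**
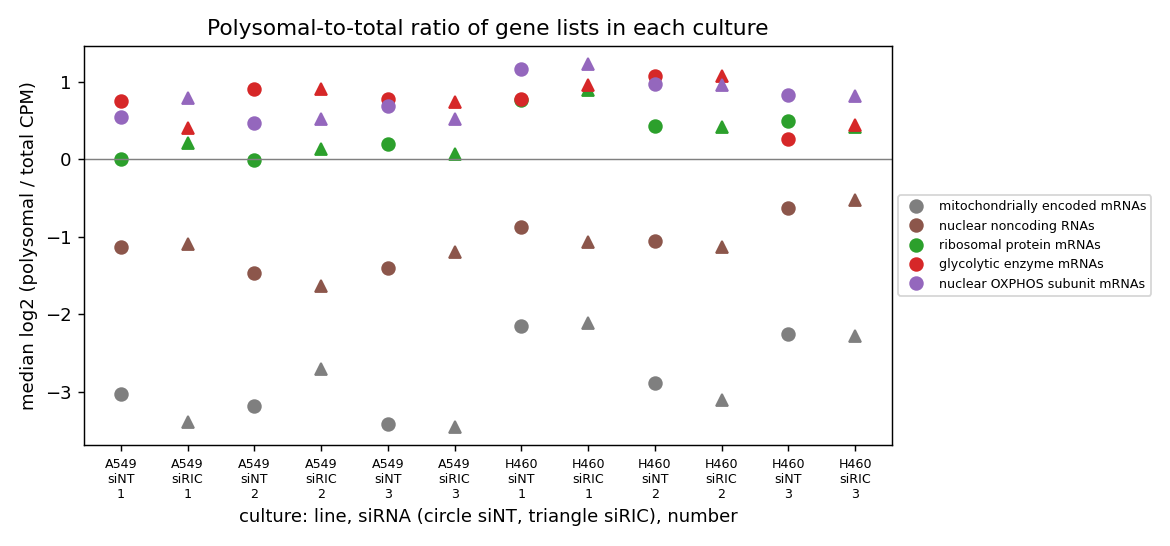
Median log2 ratio of polysomal to total CPM (vertical axis) of 5 gene lists in each of the 12 cultures (horizontal axis: line, siRNA and number), with a color for each list, circles for siNT and triangles for siRIC. Glycolytic genes lay at 0.270 and 0.441 in the H460 cultures of number 3 and at 0.777 to 1.08 in the other H460 cultures.

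In A549 total RNA, RICTOR changed by −1.38 ± 0.23 (adjusted p = 0.0159) and 50 genes in all passed the test. SCEL, a precursor of the cornified envelope, rose by 1.23 ± 0.16 (adjusted p = 0.00283), and CITED4, a coactivator that binds CBP and p300, rose by 1.25 ± 0.21 (adjusted p = 0.0170). AREG, a ligand of the EGF receptor, rose by 0.84 ± 0.16 and CCN2, a matricellular protein and YAP target, by 0.84 ± 0.16 (both adjusted p = 0.0295). SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, rose by 0.87 ± 0.16 (adjusted p = 0.0267) and MARCHF4, a membrane E3 ligase, by 0.92 ± 0.19 (adjusted p = 0.04997). Falls of similar size were measured for CCNG1, cyclin G1 (−1.41 ± 0.16), and UPK3B, a uroplakin (−1.21 ± 0.14), both with adjusted p = 0.000818, and for QDPR, dihydropteridine reductase (−1.20 ± 0.15, adjusted p = 0.00121). HR, a transcriptional corepressor, changed by −1.23 ± 0.24 (adjusted p = 0.0381) and MDGA1, a GPI-anchored adhesion protein, by −1.10 ± 0.22 (adjusted p = 0.0457). ARNT was at −0.72 ± 0.16 (adjusted p = 0.0754), which passed with the replicate block (adjusted p = 0.0189), and HIF1A was at −0.15 ± 0.15 (adjusted p = 1).

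Of 15396 genes tested in A549 total RNA, 12 rose and 38 fell, and 1048 had an unadjusted p under 0.05. The replicate block gave 87 higher and 171 lower genes and kept all 50 calls, DESeq2 gave 164 and no filter on low counts 257. The block with only the groups compared, a fit added after seeing the data, gave 1309 higher and 1485 lower genes. Without 1 library the count moved to 31 and 30 (siNT polysomal numbers 1 and 3), 12, 15 and 12 (siNT total numbers 1, 2 and 3), 172 (siRIC polysomal number 1) and 7, 8 and 15 (siRIC total numbers 1, 2 and 3). RICTOR itself lost its call without siNT total number 1 (adjusted p = 0.102) or 3 (0.0803) and without siRIC total number 1 (0.123), 2 (0.0984) or 3 (0.0601). SCEL, CCNG1, UPK3B and QDPR passed in all 12 such fits. CITED4 lost its call in 4 of 12, SPRY2 and CCN2 in 6, AREG in 7, HR in 8, MDGA1 in 9 and MARCHF4 in 10, with highest adjusted p of 0.136, 0.176, 0.246, 0.211, 0.214, 0.271 and 0.266, respectively.

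Among the gene lists, NRF2 targets fell together in A549 total RNA. Of 30 measured members of this list of antioxidant and detoxification genes, 1 lay above 0 and the median was −0.26. AKR1B10 and AKR1C2, both aldo-keto reductases, fell by 0.76 ± 0.14 (adjusted p = 0.0255) and 0.79 ± 0.16 (adjusted p = 0.0493), which makes 2 members called over all genes and 8 adjusted over the list alone. The list passed camera (adjusted p = 9.64e-14) and kept its call (adjusted p = 0.000772 with an estimated correlation), and fry gave 0.000141. AKR1C1 at −0.75 ± 0.17 (adjusted p = 0.0883) and AKR1C3 at −0.70 ± 0.19 (adjusted p = 0.188) passed with the replicate block (0.00442 and 0.0128), and the division of counts between these near-identical genes is uncertain. Without 1 library, AKR1B10 lost its call in 5 of 12 fits (highest adjusted p = 0.182) and AKR1C2 in 9 (highest 0.255). HIF targets had a median of −0.16 with 0 of 45 called and 1 lower adjusted over the list alone (camera adjusted p = 0.000639, adjusted p = 0.392 with an estimated correlation). CA12, a carbonic anhydrase, was at −0.61 ± 0.15 (adjusted p = 0.116; replicate block 0.00503) and NDRG1 at −0.63 ± 0.18 (adjusted p = 0.233).

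Immediate early and feedback genes had a median of 0.22 in A549 total RNA, with 1 of 20, SPRY2, called over all genes and 7 higher adjusted over the list alone (camera adjusted p = 1.12e-06, adjusted p = 0.155 with an estimated correlation). DUSP4, a MAP kinase phosphatase, was at 0.65 ± 0.14 (adjusted p = 0.0543) and DUSP6 at 0.71 ± 0.18 (adjusted p = 0.140), and both passed with the replicate block (0.00784 and 0.0102). NF-κB and inflammation genes had a median of 0.29, 0 of 14 called and 2 higher adjusted over the list alone (camera adjusted p = 0.000685, adjusted p = 0.183 with an estimated correlation), with CXCL8 at 1.21 ± 0.34 (adjusted p = 0.203; replicate block 0.0151). P53 targets had a median of −0.14 with 1 of 29, CCNG1, called and 1 adjusted over the list alone (camera adjusted p = 0.000207, adjusted p = 0.155 with an estimated correlation). Glycolysis (median −0.20), fatty acid synthesis (−0.16), cholesterol synthesis (−0.10) and oxidative phosphorylation (−0.06) had no member called by either count and passed camera with adjusted p = 0.00306, 0.00503, 0.0242 and 0.0152, against adjusted p = 0.700, 0.520, 0.155 and 0.764 with an estimated correlation. Sphingolipid genes had a median of −0.05, with 26 of 57 above 0, 0 called by either count and adjusted p = 0.241. CERS1 and CERS4, ceramide synthases, were at −0.58 ± 0.19 (adjusted p = 0.343) and −0.47 ± 0.19 (adjusted p = 0.594). The replicate block added ribosomal proteins (adjusted p = 0.0350), translation factors with 5′ TOP mRNAs (0.0234) and ribosome biogenesis (0.0268) to the lists passing. Without the block these had adjusted p = 0.878, 0.759 and 0.7645 with an estimated correlation.

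**Figure D3:**
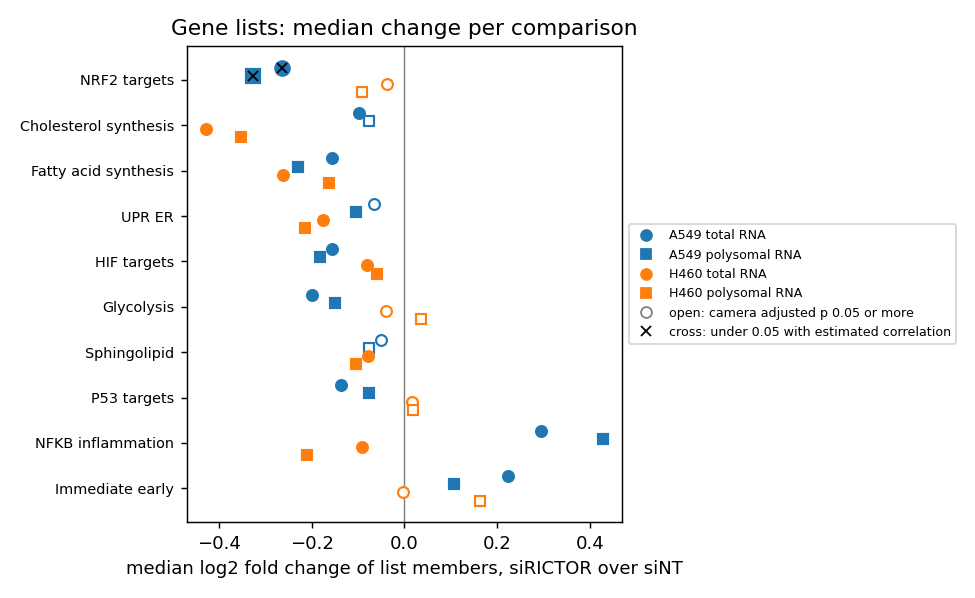
Median log2 fold change, siRIC against siNT (horizontal axis), of 10 gene lists (vertical axis) in total RNA (circles) and polysomal RNA (squares) of A549 (blue) and H460 (orange). Filled symbols mark a camera adjusted p under 0.05 and crosses those also passing with an estimated correlation, which held for NRF2 targets in A549 alone, at −0.26 in total and −0.33 in polysomal RNA (the latter not without siRIC polysomal number 1).

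In A549 polysomal RNA, ARNT fell by 0.97 ± 0.16 (adjusted p = 0.0107) and RICTOR changed by −1.495 ± 0.23 (adjusted p = 0.00700), while HIF1A was at −0.12 ± 0.15 (adjusted p = 0.804). SCEL rose by 1.73 ± 0.16 (adjusted p = 0.000104) and CITED4 by 1.14 ± 0.21 (adjusted p = 0.0151). EREG, a ligand of the EGF receptor (1.01 ± 0.19), ANKRD1, a YAP target (1.06 ± 0.21), KCNF1, a potassium channel subunit (1.03 ± 0.19), and ACOX2, a peroxisomal acyl-CoA oxidase (0.98 ± 0.18), also rose, with adjusted p = 0.0164, 0.0261, 0.0151 and 0.0158. Besides RICTOR, the largest falls among the named genes were KRT4, a keratin (−2.39 ± 0.24, adjusted p = 0.000131), PDZK1, a scaffold protein (−1.56 ± 0.30, adjusted p = 0.0184), and HOGA1, a mitochondrial aldolase (−1.41 ± 0.22, adjusted p = 0.00691). They were followed by TSPAN3, a tetraspanin (−1.32 ± 0.15, adjusted p = 0.000460), and CYP4F3, a leukotriene hydroxylase (−1.31 ± 0.24, adjusted p = 0.0158).

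Altogether 34 genes rose and 70 fell in A549 polysomal RNA, with 1932 at an unadjusted p under 0.05. The replicate block gave 214 higher and 326 lower genes and kept all 104 calls, DESeq2 gave 346 and no filter on low counts 413. The added fit with the block and only the groups compared gave 126 higher and 210 lower genes. Without 1 library the count moved to 19, 55 and 54 (siNT polysomal numbers 1, 2 and 3), 69 (siNT total number 1), 456 (siRIC polysomal number 1) and 55 (siRIC polysomal number 2). The siRIC polysomal library of number 1 stood apart from the others of its group, with chi-square values per degree of freedom of 90.1 and 112 against them and 38.9 between those. The median log2 polysomal-to-total ratio of its culture was 0.285 for NRF2 targets, 0.057 for HIF targets and 0.408 for glycolytic genes. In the other 5 A549 cultures these were 0.544 to 0.653, 0.245 to 0.427 and 0.737 to 0.915. Without it 264 genes rose and 192 fell, and each gene named here as called kept its call. ARNT lost its call without siNT polysomal number 1 (adjusted p = 0.0532) or 2 (0.0521), and in the fit of only the groups compared (0.0516), which called 35 genes in all. RICTOR, SCEL, KRT4, HOGA1 and TSPAN3 passed in all 12 such fits. ANKRD1, KCNF1, EREG, PDZK1 and CYP4F3 lost their calls in 3 of 12 fits (highest adjusted p of 0.179, 0.119, 0.126, 0.0874 and 0.0762), and CITED4 and ACOX2 in 4 (0.0862 and 0.0704). The A549 total and polysomal calls shared 7 higher and 32 lower genes (0.0265 and 0.173 by chance for independent lists). The labels' protocols describe total RNA as the input of the fractions, so the lists were not treated as independent.

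NRF2 targets fell in A549 polysomal RNA too, with a median of −0.33, 4 members called lower over all genes and 10 adjusted over the list alone (camera adjusted p = 3.40e-11, adjusted p = 0.00162 with an estimated correlation). Without siRIC polysomal number 1, which stood apart, the median was −0.25 and the list passed camera (adjusted p = 1.03e-07), but not with an estimated correlation (adjusted p = 0.0666 with an estimated correlation). The called members were AKR1B10 (−0.99 ± 0.14, adjusted p = 0.00232), AKR1C2 (−0.93 ± 0.16, adjusted p = 0.0122), AKR1C1 (−0.94 ± 0.17, adjusted p = 0.0151) and UGDH, which makes UDP-glucuronate (−0.67 ± 0.14, adjusted p = 0.0336). AKR1C2 lost its call without siNT polysomal number 1 (adjusted p = 0.0719), AKR1C1 without siNT polysomal number 1 (0.0762) or 3 (0.0647) or siRIC polysomal number 2 (0.0654), and UGDH in 9 of 12 such fits (highest 0.163). HIF targets had a median of −0.18, 1 called, CA12 (−0.76 ± 0.15, adjusted p = 0.0242, lost in 5 of 12 fits without 1 library, highest 0.123), and 4 lower adjusted over the list alone (camera adjusted p = 0.000552, adjusted p = 0.476 with an estimated correlation). Without siRIC polysomal number 1 the list lost its call (median −0.08, adjusted p = 0.0653). NDRG1 at −0.74 ± 0.18 (adjusted p = 0.0814) and PGK1 at −0.46 ± 0.13 (adjusted p = 0.122) passed with the replicate block (0.0144 and 0.0245).

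NF-κB and inflammation genes had a median of 0.43 in A549 polysomal RNA, 1 called and 3 higher adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.476 with an estimated correlation). The called member was CXCL8, the chemokine interleukin-8 (1.74 ± 0.34, adjusted p = 0.0236), which lost its call without siNT polysomal number 1 (0.119), 2 (0.130) or 3 (0.0699). CXCL8 failed at least 1 part of the filter for the largest rises, a mean of at least 5 CPM and the same sign in all 3 pairs. Immediate early genes had a median of 0.11, 1 called and 5 higher adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.572 with an estimated correlation), with SPRY2 at 0.82 ± 0.17 (adjusted p = 0.0291, lost in 6 of 12 fits, highest 0.182). AHR, the ligand-activated partner of ARNT, rose by 0.80 ± 0.17 (adjusted p = 0.0431, lost in 8 of 12 fits, highest 0.235). FOXO targets, a list that holds RICTOR itself, had a median of −0.17 with RICTOR as the member called and 4 lower adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.767 with an estimated correlation). Lysosomal genes (median −0.16), G1/S genes (−0.18), the unfolded protein response (−0.11), fatty acid synthesis (−0.23), glycolysis (−0.15) and translation factors with 5′ TOP mRNAs (−0.08) passed camera with adjusted p = 0.00788, 0.00788, 0.00788, 0.0180, 0.0113 and 0.0309. The corresponding values were adjusted p = 0.250, 0.595, 0.572, 0.595, 0.767 and 0.823 with an estimated correlation. In these lists 0 members were called over all genes, and adjusted over the list alone 1 G1/S gene was higher and 2 lower, 1 gene of fatty acid synthesis and 1 of glycolysis were lower, and 2 of the translation factors were lower. P53 targets passed (adjusted p = 0.0456) but not with the replicate block (adjusted p = 0.0705) or otherwise (adjusted p = 0.572 with an estimated correlation), and the block added mitochondrially encoded genes and mitochondrial ribosomal proteins (both 0.0432). Without the block both had adjusted p = 0.930 with an estimated correlation. Without siRIC polysomal number 1, which stood apart, the calls of NF-κB genes, lysosomal genes and P53 targets (adjusted p = 0.0653 each) were lost. So were those of G1/S genes (0.220), fatty acid synthesis (0.324) and glycolysis (0.734), and a lost call does not by itself show a smaller shift. The added mitochondrially encoded genes and mitochondrial ribosomal proteins then had medians of −0.11 and 0.00279, against −0.15 and 0.10 with that library (adjusted p = 0.459 and 0.991 without the block). Immediate early genes had a median of 0.26 (adjusted p = 0.000883, adjusted p = 0.440 with an estimated correlation), the unfolded protein response −0.19 (0.0147) and translation factors with 5′ TOP mRNAs −0.17 (0.0282), the last 2 with adjusted p = 0.978 with an estimated correlation. Oxidative phosphorylation (median −0.13) then passed (adjusted p = 0.000746, adjusted p = 0.984 with an estimated correlation). Sphingolipid genes had a median of −0.08, with 23 of 57 above 0 and adjusted p = 0.507, UGCG, glucosylceramide synthase, being at 0.56 ± 0.16 (adjusted p = 0.137).

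The polysomal-to-total ratio asks whether RICTOR depletion moved an mRNA onto or off polysomes, relative to other mRNAs, beyond its change in total RNA. Libraries were scaled by TMM, so a shift in polysome loading shared by most mRNAs could not be seen in either line. In A549, RICTOR was at −0.11 ± 0.32, ARNT at −0.25 ± 0.23 and HIF1A at 0.04 ± 0.22 (adjusted p = 1 for each), and CERS1 at 0.58 ± 0.26 (adjusted p = 1). The edgeR test called 0 genes, with 177 at an unadjusted p under 0.05, 0 with the replicate block, 1 with DESeq2 and 1 with a replicate block within cultures. With no filter on low counts it called 31 genes higher and 28 lower. Without siNT polysomal number 2 or siRIC polysomal number 2 it called 2. No gene list passed camera, while with the replicate block ribosomal proteins (median 0.09), G1/S genes (−0.09), YAP targets (−0.10), lysosomal genes (−0.10) and ribosome biogenesis (−0.08) passed at adjusted p = 0.0453, each 0.0962 without it. Each had adjusted p = 0.983 with an estimated correlation and no block. Without siRIC polysomal number 1, and without the block, the medians were 0.01, −0.03, −0.10, −0.04 and −0.05 (adjusted p = 0.922, 0.849, 0.649, 0.649 and 0.922). In simulated data with independently drawn libraries, 47.8% of 2-fold changes in the ratio were recovered.

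In H460 total RNA, RICTOR was at −1.52 ± 0.30 and ARNT at −0.52 ± 0.18, lower in all 3 pairs of equal number, without passing the test over all genes (adjusted p = 1 for both). HIF1A was at −0.12 ± 0.24. Cholesterol synthesis genes were the most shifted list, with a median of −0.43 and 0 of 24 members above 0. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, was at −0.85 ± 0.33, MSMO1 at −0.80 ± 0.39, HMGCS1 at −0.62 ± 0.30 and FDFT1, squalene synthase, at −0.40 ± 0.16. Fatty acid synthesis genes had a median of −0.26 with 2 of 20 above 0, among them the desaturases FADS2 at −0.90 ± 0.37 and SCD at −0.52 ± 0.23. Genes of the unfolded protein response had a median of −0.18 with 1 of 23 above 0, including MANF at −0.57 ± 0.22 and HERPUD1 at −0.39 ± 0.16. Sphingolipid genes had a median of −0.08 with 18 of 56 above 0, including KDSR, which makes dihydrosphingosine (−0.46 ± 0.19), and CERS4 (−0.87 ± 0.41), and each of these genes had adjusted p = 1.

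The edgeR test called 0 of 14586 genes in H460 total RNA, with 167 at an unadjusted p under 0.05, 0 with the replicate block, 4 with DESeq2 and 3 with no filter on low counts, and 1 without siNT polysomal number 3 or siNT total number 1. The lists were tested with camera, which gave adjusted p = 7.02e-17 for cholesterol synthesis, 1.63e-07 for fatty acid synthesis, 4.88e-07 for the unfolded protein response and 0.00463 for sphingolipid genes. These became adjusted p = 0.254, 0.254, 0.447 and 0.852 with an estimated correlation, and 0 members were called over all genes and 0 adjusted over the list alone. HIF targets (median −0.08), oxidative phosphorylation (−0.06) and NF-κB genes (−0.09) passed with adjusted p = 0.00629, 0.0212 and 0.0242, against adjusted p = 0.769, 0.927 and 0.852 with an estimated correlation. The replicate block added translation factors with 5′ TOP mRNAs (0.0703 without and 0.0393 with it, adjusted p = 0.852 with an estimated correlation and no block). NRF2 targets had a median of −0.04 (adjusted p = 0.230).

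A fit of the H460 total libraries alone with the replicate block, chosen after seeing the data and the most generous of 10 settings tried, gave smaller errors for the same genes. It had 2 residual degrees of freedom. RICTOR was then at −1.54 ± 0.10 (adjusted p = 0.000154), with adjusted p from 0.000154 to 1 over the settings other than leaving out single libraries. ARNT was at −0.54 ± 0.07 (adjusted p = 0.00514, and from 0.00514 to 1 over those settings), INSIG1 had adjusted p = 0.00631, FADS2 0.000275 and KDSR 0.00514. This fit called 136 genes higher and 381 lower.

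In H460 polysomal RNA, RICTOR was at −1.90 ± 0.31 (adjusted p = 0.620), ARNT at −0.66 ± 0.18 (adjusted p = 1) and HIF1A at −0.18 ± 0.24 (adjusted p = 1). Cholesterol synthesis genes had a median of −0.35 with 1 member above 0, including MSMO1 at −0.94 ± 0.39, INSIG1 at −0.82 ± 0.33, CYP51A1 at −0.55 ± 0.22 and FDFT1 at −0.41 ± 0.16. The unfolded protein response had a median of −0.21, with MANF at −0.62 ± 0.22 and the chaperone HSPA5 at −0.39 ± 0.21, and fatty acid synthesis a median of −0.16, with SCD at −0.56 ± 0.23. Sphingolipid genes had a median of −0.10 with 16 above 0, including KDSR at −0.47 ± 0.19 and ACER3, an alkaline ceramidase, at −0.37 ± 0.17, each with adjusted p = 1.

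In that comparison the edgeR test called 0 genes, with 252 at an unadjusted p under 0.05, 0 with the replicate block, 1 with DESeq2 and 7 with no filter on low counts, and 1 without siRIC polysomal number 3. Camera gave adjusted p = 2.09e-13 for cholesterol synthesis, 3.03e-06 for the unfolded protein response, 4.42e-05 for fatty acid synthesis, 0.00382 for NF-κB genes (median −0.21) and 0.00955 for sphingolipid genes. These were adjusted p = 0.401, 0.401, 0.401, 0.670 and 0.836 with an estimated correlation, and 0 members were called by either count. Nuclear noncoding RNAs (0.0384), oxidative phosphorylation (0.0384) and HIF targets (0.0438) also passed, against adjusted p = 0.836, 0.982 and 0.836 with an estimated correlation, and the replicate block added AHR targets (0.0783 without and 0.0404 with it, adjusted p = 0.401 with an estimated correlation and no block). Without the 2 H460 polysomal libraries of number 3, which stand apart, the calls of sphingolipid genes (adjusted p = 0.147), NF-κB genes (0.292), oxidative phosphorylation (0.147) and HIF targets (0.0551) were lost, while cholesterol synthesis passed (3.24e-07). The added fit with the block and only these groups called 22 genes higher and 78 lower, with RICTOR at −1.85 ± 0.16 (adjusted p = 0.000166, and from 4.49e-05 with DESeq2 to 1 over the settings other than leaving out single libraries). ARNT, at −0.66, was called in this added fit but not in the reported one.

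For the polysomal-to-total ratio in H460, immediate early genes had a median of 0.12, with 20 of 21 above 0, including KLF2 at 0.48 ± 0.31 and EGR1 at 0.31 ± 0.28, both transcription factors. The list passed camera (adjusted p = 0.0391, adjusted p = 0.987 with an estimated correlation, 0.0156 with the replicate block), but not without the 2 polysomal libraries of number 3 (adjusted p = 0.0727). RICTOR was at −0.38 ± 0.43, ARNT at −0.14 ± 0.26 and HIF1A at −0.06 ± 0.34 (adjusted p = 1 for each). The edgeR test called 0 genes, with 89 at an unadjusted p under 0.05, 0 with the replicate block, 1 with DESeq2 and 3 with no filter on low counts, and 1 without siNT total number 1 or siRIC polysomal number 3. In simulated data with independently drawn libraries, 5.97% of 2-fold changes were recovered. Most changes of that size were missed there, so the lack of calls does not show their absence.

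The mean effect over both lines asks which genes moved on average over A549 and H460, and a call in it does not show that both lines moved. In total RNA, RICTOR (−1.46 ± 0.20, adjusted p = 0.00136), CCNG1 (−1.01 ± 0.13, adjusted p = 0.00136), QDPR (−0.94 ± 0.13, adjusted p = 0.00166) and TSPAN3 (−0.78 ± 0.12, adjusted p = 0.00536) fell. PSEN2, a subunit of gamma-secretase (−0.82 ± 0.17, adjusted p = 0.0488), TMUB2 (−0.77 ± 0.14, adjusted p = 0.0167) and ARNT (−0.63 ± 0.12, adjusted p = 0.0313) fell as well. PTX3, a secreted pentraxin (1.05 ± 0.20, adjusted p = 0.0313), PSKH1, a protein kinase (0.52 ± 0.10, adjusted p = 0.0457), and ANKRD33B (0.48 ± 0.10, adjusted p = 0.0494) rose. HIF1A was at −0.15 ± 0.15. In polysomal RNA, RICTOR (−1.70 ± 0.20), TSPAN3 (−1.12 ± 0.12), QDPR (−1.07 ± 0.13), CCNG1 (−0.97 ± 0.13), ARNT (−0.82 ± 0.12) and AKR1B10 (−0.55 ± 0.10) fell with adjusted p = 0.000132, 5.77e-05, 0.000212, 0.000560, 0.00132 and 0.0105. PSEN2 (−0.86 ± 0.16, adjusted p = 0.0222) and ATP9A, a flippase (−0.84 ± 0.16, adjusted p = 0.0162), also fell, and PSKH1 (0.79 ± 0.11, adjusted p = 0.000478) and ANKRD33B (0.49 ± 0.10, adjusted p = 0.0489) rose.

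Over both lines, 3 genes rose and 18 fell in total RNA and 2 rose and 20 fell in polysomal RNA, with 668 and 1058 at an unadjusted p under 0.05. The replicate block gave 80 and 115 genes, DESeq2 62 and 98 and no filter on low counts 71 and 88. The added fit with the block and only the groups compared gave 1067 higher and 1183 lower genes in total RNA and 43 and 74 in polysomal RNA. With DESeq2 size factors 94.1% and 95.2% of the calls were falls, against 85.7% and 90.9%. In polysomal RNA the fit of only the groups compared called 0 genes, against 22, and in total RNA it called 196, against 21. The calls in total and polysomal RNA shared 2 higher and 14 lower genes. Leaving out 1 library moved the count in total RNA to 11 (A549 siNT polysomal number 1), 9, 10 and 11 (A549 siNT total numbers 1, 2 and 3), 5, 7 and 11 (A549 siRIC total), 10, 6 and 8 (H460 siNT total) and 10, 13 and 5 (H460 siRIC total). In polysomal RNA it moved to 14 (A549 siNT polysomal number 3) and 49 (H460 siNT polysomal number 3). RICTOR, CCNG1, QDPR and TSPAN3 passed in all 24 fits of both fractions. These fits took the spread from total and polysomal libraries together, and none of these genes was called in the polysomal fit of only the groups compared. ARNT passed in all 24 in polysomal RNA and lost its call in 12 of 24 in total RNA, with adjusted p = 0.0515 without A549 siNT polysomal number 1 and up to 0.140 without A549 siRIC total number 2. PTX3, PSKH1, ANKRD33B, PSEN2 and TMUB2 lost their calls in total RNA in 10, 19, 20, 18 and 8 of 24 fits (highest adjusted p of 0.139, 0.228, 0.213, 0.172 and 0.102). In polysomal RNA, ANKRD33B, PSEN2 and ATP9A lost theirs in 21, 7 and 4 fits (highest 0.177, 0.0780 and 0.0904).

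For the mean of both lines, NRF2 targets were lower in total RNA (median −0.19, camera adjusted p = 1.09e-09, adjusted p = 0.00232 with an estimated correlation) and in polysomal RNA (−0.16, adjusted p = 5.99e-08, adjusted p = 0.00539 with an estimated correlation). Without A549 siRIC polysomal number 1 the latter was adjusted p = 0.0739 with an estimated correlation. Within single lines, NRF2 targets passed camera in both fractions of A549 and in neither fraction of H460. The mean therefore does not show a fall of this list in each line. In polysomal RNA 1 member, AKR1B10, was called over all genes and 4 adjusted over the list alone. Cholesterol synthesis genes had medians of −0.29 and −0.20 (adjusted p = 7.67e-11 and 1.16e-07), with 0 called over all genes and 2 and 5 lower adjusted over the list alone, and adjusted p = 0.0861 and 0.154 with an estimated correlation. INSIG1 was at −0.57 ± 0.18 in total and −0.59 ± 0.18 in polysomal RNA (adjusted p = 0.570 and 0.337, and 0.00812 and 0.00577 with the replicate block). Sphingolipid genes had medians of −0.09, with 19 of 59 above 0, and −0.08 (adjusted p = 0.0213 and 0.0315, adjusted p = 0.507 and 0.550 with an estimated correlation). In polysomal RNA the call was lost without the 2 H460 libraries of number 3 (adjusted p = 0.0954), and without A549 siRIC polysomal number 1 the median was −0.13 (adjusted p = 0.0226). ACER3, CERS4 and KDSR were at −0.35 ± 0.11, −0.68 ± 0.23 and −0.31 ± 0.12 in total RNA (adjusted p = 0.558, 0.792 and 0.975), and CERS4 passed with the replicate block (0.0267). Lists passing camera numbered 10 and 9, of which 1 and 1 passed with an estimated correlation. The replicate block added AHR targets, YAP targets and lysosomal genes (0.0458 each) and ribosome biogenesis (0.0286) in total RNA. Without the block these had adjusted p = 0.182, 0.834, 0.620 and 0.817 with an estimated correlation. For the ratio, RICTOR was at −0.24 ± 0.28, ARNT at −0.19 ± 0.17 and HIF1A at −0.01 ± 0.21 (adjusted p = 1). The edgeR test called 0 genes in it, with 224 at an unadjusted p under 0.05, 0 with DESeq2, 0 with the replicate block and 1 without H460 siNT total number 1. With no filter on low counts it called 23 genes higher and 17 lower.

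The difference between lines, H460 minus A549, asks whether siRIC acted differently in them. RICTOR differed by −0.14 ± 0.39 in total and −0.40 ± 0.40 in polysomal RNA, and ARNT by 0.19 ± 0.24 and 0.31 ± 0.24 (adjusted p = 1 for each). NRF2 targets differed with a median of 0.27 in total RNA (camera adjusted p = 1.70e-07, adjusted p = 0.00778 with an estimated correlation) and 0.35 in polysomal RNA (adjusted p = 1.87e-07, adjusted p = 0.00734 with an estimated correlation). Without A549 siRIC polysomal number 1 the polysomal median was 0.21 (adjusted p = 2.88e-06, adjusted p = 0.0546 with an estimated correlation). AKR1B10 differed by 0.72 ± 0.19 and 0.89 ± 0.19 (adjusted p = 1 and 0.249, the latter 0.0133 with the replicate block), and 1 and 2 members were higher adjusted over the list alone. Cholesterol synthesis genes differed by a median of −0.33 and −0.29 (adjusted p = 3.64e-06 and 0.000330, adjusted p = 0.277 and 0.550 with an estimated correlation). Immediate early genes differed by −0.42 in total RNA (adjusted p = 1.70e-07, adjusted p = 0.0740 with an estimated correlation), with EGR1 at −1.19 ± 0.29 and SPRY2 at −0.70 ± 0.24 (adjusted p = 1 for both) and 1 member lower adjusted over the list alone.

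The edgeR test called 1 gene in the differences between lines, DCLK1, a microtubule-associated kinase, in polysomal RNA (−3.29 ± 0.48, adjusted p = 0.00934, 0.0133 with the replicate block). Its mean level was 0.129 CPM ± 0.0154 (SD, n = 3) with siNT and 0.939 ± 0.436 with siRIC in A549, close to the floor, and 14.7 ± 3.90 and 10.5 ± 2.50 in H460. DCLK1 lost its call without A549 siNT polysomal number 1 (adjusted p = 0.119), 2 (0.1003) or 3 (0.0574) or siRIC polysomal number 1 (0.0637), and the count became 2 without A549 siRIC polysomal number 3 or H460 siRIC polysomal number 3. With the replicate block 3 genes were called and with DESeq2 9, and 578 had an unadjusted p under 0.05. In total RNA edgeR called 0 genes (382 at an unadjusted p under 0.05, 0 with the block, 7 with DESeq2, 1 without H460 siNT total number 1), and for the ratio 0 (222, 0 and 4). With no filter on low counts the calls were 52 in total RNA, 47 in polysomal RNA and 39 for the ratio. The added fit with the block and only the groups compared called 287 genes higher and 261 lower in total RNA, and 3 higher and 1 lower in polysomal RNA. The block added the unfolded protein response and G1/S genes in total RNA (0.0175 each), FOXO targets in polysomal RNA (0.0365) and ribosomal proteins for the ratio (0.0170). Without the block these had adjusted p = 0.804, 0.842, 0.837 and 0.958 with an estimated correlation. Without A549 siRIC polysomal number 1 the median of ribosomal proteins for the ratio went from −0.09 to −0.00218 (adjusted p = 0.9504 without the block). FOXO targets in polysomal RNA then passed with a median of 0.26 (adjusted p = 0.0417, adjusted p = 0.947 with an estimated correlation).

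Across 13562 genes measured in both lines, which are not independent replicates, log2 fold changes of the lines correlated with a Spearman rho of 0.204 in total RNA, 0.179 in polysomal RNA and 0.0759 for the ratio, and a Pearson r of −0.0818, 0.184 and −0.0812. No gene was called by edgeR in both lines, as H460 had 0 calls in both fractions (167 and 252 at an unadjusted p under 0.05), and DESeq2 called 1 gene in both lines in each fraction. Of the 38 genes called in A549 total RNA and measured in H460, 31 had the same sign there, and in polysomal RNA 69 of 87. In the added fits with the replicate block and only the groups compared, 57 genes were higher and 176 lower in both lines in total RNA and 16 had opposite signs, where independent lists would share 12.5 and 36.4. In polysomal RNA 5 were higher and 15 lower in both and 3 opposite, where independent lists would share 0.185 and 0.754.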

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

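The test of NRF2 targets without the AKR1C genes and the list tests without the A549 siRIC polysomal library of number 1, which stands apart, or without the 2 H460 polysomal libraries of number 3 were chosen only after the results were seen. Each result of this part was singled out because the effect of siRIC differed between H460 and A549 by the test of the difference itself, with values as H460 minus A549.

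NRF2 targets, higher in H460 relative to A549 by a median of 0.27 in total RNA (camera adjusted p = 1.70e-07) and 0.35 in polysomal RNA (adjusted p = 1.87e-07), were the list whose difference also passed in both fractions with an estimated correlation (adjusted p = 0.00778 and 0.00734, the latter 0.0546 without that A549 library). In A549 total RNA the list median of −0.26 lay at the 0.01 percentile of 10000 random lists matched on expression, the smallest these can give, with random medians from −0.19 to 0.03, which argues against a shift shared by abundant genes as its whole cause. Leaving out each A549 total RNA library in turn gave at most adjusted p = 1.00e-10 over 6 fits with the preset correlation. This argues against a single A549 total RNA library as the cause of the fall in that fraction. It was not run with an estimated correlation, and it left out no polysomal or H460 library, so it does not cover the difference between lines. Without AKR1C1, AKR1C2 and AKR1C3, all 3 lower, the list had a median of −0.24 with 26 of 27 members lower (camera adjusted p = 4.22e-10). The list then had adjusted p = 0.0119 with an estimated correlation. These values argue against the division of counts between AKR1C paralogs as the whole cause of the fall, less strongly with an estimated correlation. An effect of RICTOR depletion, which the design names, unintended targets of the siRNA and culture conditions stay open and were not tested on this list.

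In total RNA, immediate early genes differed by a median of −0.42 (adjusted p = 1.70e-07, adjusted p = 0.0740 with an estimated correlation). Cholesterol synthesis genes differed by −0.33 in total RNA (adjusted p = 3.64e-06) and −0.29 in polysomal RNA (adjusted p = 0.000330), with adjusted p = 0.277 and 0.550 with an estimated correlation. NF-κB and inflammation genes differed by −0.48 (adjusted p = 0.000208) and −0.53 (adjusted p = 0.00101), with adjusted p = 0.215 and 0.462 with an estimated correlation. P53 targets differed by 0.22 (adjusted p = 0.00101) and 0.14 (adjusted p = 0.0493), with adjusted p = 0.0740 and 0.462 with an estimated correlation. Translation factors with 5′ TOP mRNAs differed by 0.19 (adjusted p = 0.00125) and 0.14 (adjusted p = 0.0449), with adjusted p = 0.556 and 0.837 with an estimated correlation. In polysomal RNA alone, G1/S genes differed by 0.20 (adjusted p = 0.00241), glycolysis by 0.22 (adjusted p = 0.0236) and mitochondrial ribosomal proteins by −0.11 (adjusted p = 0.0493), with adjusted p = 0.837, 0.837 and 0.874 with an estimated correlation. Without the A549 siRIC polysomal library of number 1 the polysomal calls of G1/S genes (adjusted p = 0.0567), glycolysis (0.619), mitochondrial ribosomal proteins (0.875) and P53 targets (0.0663) were lost, and without the 2 H460 polysomal libraries of number 3 that of mitochondrial ribosomal proteins (0.0634). A lost call does not by itself show a smaller difference. For the polysomal-to-total ratio, immediate early genes differed by 0.27 (adjusted p = 0.0362, adjusted p = 0.958 with an estimated correlation), and without the A549 library this call was lost (adjusted p = 0.778). DCLK1 differed by −3.29 ± 0.48 in polysomal RNA (edgeR adjusted p = 0.00934, 0.0637 without the A549 library), with A549 levels close to the floor.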

How the results depend on the processing

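The replicate block with only the groups compared, the fit without the 2 H460 polysomal libraries of number 3, the replicate block with that removal, and list tests without the A549 siRIC polysomal library of number 1 were tests chosen only after the results were seen. No alternative reversed the direction of a named gene that was called in the reported fit or in the alternative. Changes of sign in genes called in neither were not counted. Of the effects of named genes, 38 failed in the reported fit but passed with the replicate block, and 282 stayed on their side of the threshold. DESeq2 gained 28 and kept 292. Scaling by DESeq2 size factors kept 316 and lost 4, and leaving out structural and mitochondrial RNAs kept 309 and lost 3. Neither moved a count of called genes by over 1.5 times, and all 24 libraries in the fit of the ratio changed none of 33 named effects. Fits of only the groups compared lost 21 named calls and gained 18, and no filter on low counts lost 6 and gained 21. The cause of each moved count was not tested. Depth limits genes near the floor, such as DCLK1 in A549 at 0.129 CPM.

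With DESeq2 the calls in A549 were 164 in total RNA, 346 in polysomal RNA and 1 for the ratio, and in H460 4, 1 and 1. For the mean of both lines they were 62 and 98 and for the difference between lines 7, 9 and 4, and 1 gene was called in both lines in each fraction. With no filter on low counts they were 257, 413 and 59 in A549, 3, 7 and 3 in H460, 71, 88 and 40 for the mean, and 52, 47 and 39 for the difference. With the replicate block they were 258 and 540 in A549 total and polysomal RNA, 5187 for polysomal against total RNA in H460, 80 and 115 for the mean and 3 for the difference in polysomal RNA, and with a replicate block within cultures 1 for the A549 ratio. The block moved no other count by over 1.5 times, and changed no call of a gene or list described other than those given beside their results. Fits of only the groups compared gave 152 and 35 in A549, 3 in H460 total RNA, 2146 for polysomal against total RNA in H460, 196 and 0 for the mean and 2 and 0 for the difference. Of the gene list tests, 10 passed with an estimated correlation and 51 with fry, against 108.

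The added replicate block with only the groups compared gave 2794 and 336 calls in A549, 517 and 100 in H460, 2250 and 117 for the mean and 548 and 4 for the difference, with 233 and 20 genes called in the same direction in both lines. In a single line these fits had 2 residual degrees of freedom. Without the 2 H460 polysomal libraries of number 3 the calls were 2 and 2 in H460 total and polysomal RNA, 7031 for polysomal against total RNA in H460, 57 and 52 for the mean and 2 and 3 for the difference. With the replicate block and that removal they were 43, 4 and 1 in H460, 8157 for polysomal against total RNA, 265, 322 and 1 for the mean and 16, 15 and 1 for the difference. For these added fits the cause was not tested either. Without the A549 siRIC polysomal library of number 1, 51 list tests passed in the siRIC comparisons of A549 and of both lines, against 55.

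Leaving out 1 library gave 7 to 172 calls in A549 total RNA, 19 to 456 in A549 polysomal RNA, and 0 to 2 for the A549 ratio. It gave 0 to 1 in H460 total RNA, in H460 polysomal RNA and for the H460 ratio, and 1832 to 4580 for polysomal against total RNA in H460. For the mean of both lines it gave 5 to 30 in total RNA, 14 to 49 in polysomal RNA and 0 to 1 for the ratio, and for the difference 0 to 1 in total and 0 to 2 in polysomal RNA.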

Other observations

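The tests chosen only after the results were seen are the splits of the added fits with the replicate block, the 3 tests on the low counts in H460 and the 2 tests on calls being mostly falls. The added fits of A549 and H460 total and polysomal RNA each had 2 residual degrees of freedom. Across them, 15 genes were called in the same direction in all 4, with 12 lower and 3 higher. Besides RICTOR (mean log2 fold change −1.58) and ARNT (−0.72), these were QDPR (−0.9998), CCNG1 (−0.99), TSPAN3 (−0.94), SLC25A22, a mitochondrial glutamate carrier (−0.91), and PSEN2 (−0.84), which were lower. Also lower were ATP9A (−0.79), ANXA5, annexin A5 (−0.75), SUCLA2, a subunit of succinyl-CoA synthetase (−0.69), IL1R1 (−0.59) and VAPA, an endoplasmic reticulum contact site protein (−0.53). ANKRD52 (0.56), PSKH1 (0.66) and CITED4 (0.89) were higher. Averaged over both lines in total RNA, fatty acid synthesis genes had a median of −0.19 (camera adjusted p = 5.19e-07), the unfolded protein response −0.16 and HIF targets −0.12 (both adjusted p = 4.16e-05), with adjusted p = 0.0861, 0.182 and 0.159 with an estimated correlation.

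Few or no genes were called in H460, although RICTOR was lower there too. That the 2 polysomal libraries of number 3 alone account for the few calls in H460 total RNA is argued against, since without them 2 genes were called there. A count of calls does not measure the spread, and the removal also left fewer residual degrees of freedom. The part of these libraries in the spread therefore stays open. Weaker depletion of RICTOR mRNA in H460 is argued against only by the added blocked fit of total RNA, where the difference between lines was −0.14 with an upper 95% bound of 0.176. The fit without the block (−0.14 ± 0.39) by itself does not exclude it. RICTOR protein was not measured in these data, so weaker depletion of the protein stays open. In H460 total RNA, the fit with the block and only the groups compared gave 517 calls. Its median SE among genes of at least 5 CPM was 0.0681, against 0.250 in the reported fit. Spread shared between libraries of the same number may be a candidate explanation, but this fit also left out the polysomal libraries. In H460 total RNA, r between siNT and siRIC libraries of the same number was 0.0675 to 0.242. The block alone gave 0 calls, the groups compared alone 3, and the block without the 2 polysomal libraries of number 3 gave 43. Those 2 libraries may therefore add to the shared spread, and the fit with 517 was the most generous of 10 settings.

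Calls in the mean of both lines were mostly falls in the fit without a block, 85.7% of 21 in total RNA. The added fit with the block and only the groups compared was close to balanced there, with 1067 higher and 1183 lower genes, and gave 43 and 74 in polysomal RNA. Normalization could not be told apart, since DESeq2 size factors, with 94.1% falls, moved the median log2 fold change of all genes only from 0.0030 to −0.0061. Unintended targets of the siRNA would also give falls, and with no sequence of the siRNA used here this could not be told apart from an effect of RICTOR depletion, which stays open as untested.

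Other splits of the samples into groups of the same sizes were counted for each comparison. In the single lines 10 splits exist, too few for a share under 0.05. The real split called 50 genes in A549 total RNA, 104 in polysomal RNA, 0 for the ratio and 5714 for polysomal against total RNA, and the highest other split 2, 2, 2 and 1. In H460 the real split called 0, 0, 0 and 3347 and the highest other split 1, 4501, 1 and 2. Where the real split called 0 genes, all 10 of 10 splits gave as many by construction, which tests nothing. The count of 4501 in H460 polysomal RNA points to a structure of the samples, as the 3 other splits that called any gene there kept both number-3 cultures together, while the 3 others parting all pairs called 0. In H460 total RNA 2 of the 3 other splits with a call kept them together, and splits parting all pairs reached 1. The added fits with the replicate block allow 4 splits, too few again, with 2794 against 2, 336 against 31, 517 against 2 and 100 against 0 genes.

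For the mean of both lines in total RNA, 1 of 100 splits, the real one with 21 genes, gave as many and the highest other gave 1, which excludes chance only against splits that ignore the pairs. Only some of the splits that part all pairs were among the 100 drawn. The 13 others drawn of this kind called 0, too few for a share under 0.05. Chance was not excluded in polysomal RNA, where 11 of 100 splits gave at least 22 genes and the highest other 3498, which points to a structure of the samples, since all 10 others kept the H460 number-3 cultures together and the 13 others parting all pairs called 0. For the difference between lines in polysomal RNA it was not excluded either, as 31 of 100 splits gave at least 1 gene (highest other 3946). These splits relabel the siRNA in both lines, so they stand for no effect in either line. They cannot test whether equal effects in both lines would give such a difference. Of the 30 others in polysomal RNA, 24 kept the H460 number-3 cultures together, and the 13 parting all pairs called 0. For the mean ratio and for the difference in total RNA and in the ratio the real split called 0 genes, so 100 of 100 splits gave as many by construction and nothing was tested (highest others 1, 10 and 1).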
